A study of Mus musculus with 2 samples.

How the data were processed

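Total RNA of cultured mouse tracheal epithelial cells was measured on 2 Affymetrix whole-transcript arrays, 1 from wild-type cells and 1 from Gprc5a knockout cells. Per the labels' protocols, the donor mice were 3 weeks old and of a mixed C57BL/6 and 129sv background. The cells grew in a keratinocyte serum-free medium with 5 ng/ml epidermal growth factor and 50 µg/ml bovine pituitary extract, and were in exponential phase. RNA was purified on columns with a DNase step, and 250 ng was turned into sense-strand cDNA and labelled with biotin. The platform table supplied with the data is that of an exon array summarised per transcript.

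The deposited values are on a log2 scale. The submitters' processing notes name RMA and Affymetrix Expression Console, with no versions, and RMA as commonly run corrects the background, quantile-normalizes the arrays and summarises the probes of a probe set. Whether the authors normalized these 2 arrays together or with others, which filters they applied and which genome build their annotation used are not given in the sources used here. In the deposited log2 values the sorted columns differ by at most 0.17, and the column medians are 5.98 for the wild type and 6.04 for the knockout. The values run from 1.31 to 13.06 in the wild-type column and from 1.37 to 13.11 in the knockout column. No detection calls come with the values. Quantile normalization makes the overall level of the 2 arrays equal, so a global change in RNA content could not be seen, and RMA is known to understate large ratios and to leave an unexpressed gene at a low positive value.

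The value table held 23332 probe sets. The platform annotation listed genes for 16015 of them, of which 14996 carried exactly 1 gene symbol and 1019 carried several. The 7317 others were unnamed here, and 6577 of these had ID numbers below 6000000. Of the 14996 single-symbol probe sets, 14941 were matched by Entrez ID to a RefSeq table of assembly GRCm38.p6, no symbol changed by this, and the others kept the platform's name. They stood for 14860 genes. For the 135 genes with more than 1 probe set, the one with the highest mean level was used. Among those 135 genes the differences of the probe sets spread over a median of 0.18 on the log2 scale. For 9 of the 135 genes the spread exceeded 1. No coordinates are given, because the build behind the array annotation is not stated, and the RefSeq table served only for names and for the order of genes along the chromosome.

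A difference is the knockout value minus the wild-type value on the log2 scale, and a fold is 2 raised to that difference. With 1 sample per group there is no test, no error and no p-value: the differences describe these 2 samples and have no replicate check, and the number of arrays limits the precision. Genes were counted at a threshold of 2-fold when their higher value exceeded 6.76, the median over both samples of all probe sets with a gene symbol, a limit that 7943 genes passed. A gene dim in 1 sample can pass by its value in the other, so in lists with few passing members the filter favours genes that differ. To show where unexpressed genes lie, the 800 olfactory and vomeronasal receptor genes were taken as a background set, a choice made after the data were seen. Their median was 2.88 and their 95th percentile 5.05. A ratio against a value near or below that level depends on how RMA treats background.

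Before the data were examined, 36 gene lists, the comparison of the neighbours of Gprc5a and the rule for the genes named in the text were fixed. The named genes were Gprc5a, the 14 genes with the highest and the 14 with the lowest difference above the level filter (leaving out predicted genes, small RNAs, and olfactory, vomeronasal, taste, immunoglobulin and T cell receptor genes), and up to 4 members of each list with the largest absolute difference among those above the filter, or the 2 brightest members where none passed it. Further members and genes named in the text beyond this rule were chosen after their values were seen. Of 629 list entries, 532 had a gene of their own on the array. Each list's median difference was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. The percentile describes these 2 samples and is no p-value. With 36 lists, 1.8 would be expected outside the 2.5th to 97.5th percentile by chance if the members of a list varied independently. Genes regulated together need not do so, and some lists share genes. The neighbours were the 10 genes on either side of Gprc5a, in chromosome order among genes on the array, compared by their median absolute difference.

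The scripts were tested on simulated data for 14860 genes, with each value given an SD of 0.2. Of 100 genes changed by 1.5 on the log2 scale, 97 were counted with the right sign at 2-fold, against 5 of 100 genes changed by 0.5 and 2 unchanged genes. A list of 20 genes shifted by 0.4 reached a percentile of 100, and 6 of 100 unshifted lists fell outside the central 95%. The simulated noise was independent between genes, equal at all levels and without variation between cultures. The genes changed by 1.5 or 0.5 were all placed well above the level filter. In the real data the SD of the differences was 0.58. The simulation thus tests the scripts and gives no error rates for the 2 arrays. The alternatives were median centring, removal of the intensity trend with lowess (span 0.3), quantile normalization, an offset of 32 added before the logarithm, the mean over a gene's probe sets, other level filters and fold thresholds, restriction of the lists to members above the filter, their mean, unmatched random lists and windows of 5 or 20 neighbours. A further alternative, values raised to the 95th percentile of the receptor genes, was chosen after seeing the data. A list's median or a named gene was treated as moved when it changed by 0.1 or more, so a change of sign smaller than this was not counted as a reversal, and a count when it changed by more than 1.5 times. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.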

Results

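Gene expression was compared between cultured tracheal epithelial cells of wild-type mice and of mice lacking Gprc5a, an orphan G protein-coupled receptor known as a retinoic acid-induced gene. Each genotype was represented by 1 array, so every value below is a single measurement without an error. Across 14860 genes the samples correlated with a Pearson r of 0.98, and genes are not independent replicates. The median difference over all genes was -0.03 on the log2 scale, and the central 95% of the differences ran from -0.93 to 1.18.

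The targeted gene was examined first. Gprc5a had a log2 value of 9.49 in the wild-type sample and 4.05 in the knockout sample, a difference of -5.44 or 43.3-fold. The knockout value lay below 5.05, the 95th percentile of the olfactory and vomeronasal receptor genes that stood for background, and raised to that level it gave a difference of -4.43 or 21.6-fold. The other members of the receptor family differed little. Gprc5b was 1.26-fold lower and Gprc5c 1.44-fold lower in the knockout sample, and Gprc5d was at 3.83 in the wild type and 3.52 in the knockout. Both values of Gprc5d were below background. The median difference of all 4 was -0.43 (percentile 2.85 among level-matched random lists), a value that includes the deleted gene itself and so says little about the other members.

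Beyond the targeted gene, the samples differed at many genes. Among the 7943 genes above the level filter, 367 (4.62%) were at least 2-fold higher in the knockout sample and 236 (2.97%) were at least 2-fold lower. Differences of at least 8-fold were seen for 49 higher and 32 lower genes. Without the level filter 496 genes (3.34%) were at least 2-fold higher and 314 (2.11%) lower, and of the 800 background receptor genes, also without it, 2.38% differed by 2-fold or more in either direction. These counts have no replicate check, and they include whatever separates these 2 samples besides the genotype.

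The highest differences belonged to genes that were dim in the wild-type sample and bright in the knockout sample. Timp3, an inhibitor of matrix metalloproteinases, went from 4.67 in the wild type to 11.18 in the knockout, a 91.1-fold difference. Krt18, a keratin of simple epithelia, was 88.1-fold higher, at 5.15 and 11.61. Gria3, a glutamate receptor subunit, was 77.7-fold higher, Lcn2, the antimicrobial lipocalin-2, 52.0-fold, and Gjb2, the gap junction protein connexin 26, 48.5-fold. Itm2a was 41.6-fold, Hoxb2, a homeobox transcription factor, 40.1-fold, Ddit4l 35.6-fold and the amino acid transporter gene Slc6a14 28.4-fold higher. Mr1, which presents microbial metabolites to T cells, was 26.7-fold, Plxdc2 26.0-fold, the desmosomal cadherin gene Dsg2 24.8-fold, the glutathione transferase gene Mgst1 20.4-fold and Sncg 19.7-fold higher. For 9 of these 14 genes the wild-type value lay at or below the background percentile of 5.05, so the size of the ratio depends on how low values were treated. With low values raised to that percentile these 9 were 11.1-fold to 69.95-fold higher.

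The lowest differences belonged to genes that were bright in the wild-type sample and dim in the knockout sample. Hspb8, a small heat shock protein, was at 10.65 in the wild type and 4.53 in the knockout, a 69.8-fold difference. Raet1e was 62.2-fold lower, and it belongs to a family of close paralogs whose probes may not be told apart. Igfbp7, a secreted insulin-like growth factor binding protein, was 55.5-fold lower, Scd1, the stearoyl-CoA desaturase, 50.3-fold, Sgce, a sarcoglycan, 39.7-fold, and the ephrin receptor gene Epha7 36.7-fold. Arhgdib was 35.1-fold lower, the BMP and WNT antagonist gene Sostdc1 31.4-fold, Pdpn, podoplanin, 29.5-fold, and the chemokine gene Ppbp 28.0-fold. Bmp7 was 26.6-fold, the neuronal intermediate filament gene Ina 24.9-fold and the RNA-binding protein gene Igf2bp3 18.95-fold lower. Of these 14 genes, Gprc5a included, 10 had a knockout value at or below the background percentile, and with low values raised to it these were 8.33-fold to 48.5-fold lower.

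**Figure D1:**
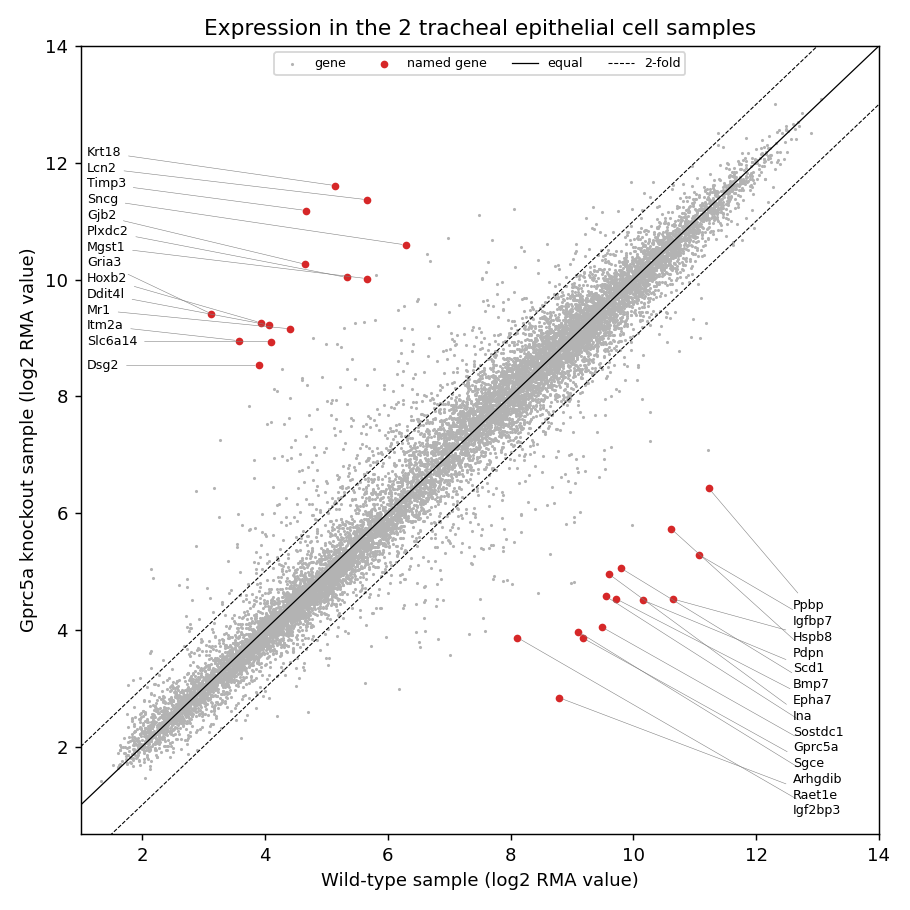
Log2 RMA value of each of 14860 genes in the wild-type sample (x axis) and the Gprc5a knockout sample (y axis); grey points are genes, red points the 28 genes with the highest and lowest differences, the solid line marks equal values and the dashed lines 2-fold differences. Gprc5a lies at 9.49 and 4.05, and the red points at the upper left and lower right lie far from the main cloud.

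Known target genes of the tumour suppressor p53 were higher in the knockout sample as a group. Of 19 measured members, 10 were at least 2-fold higher, 1 was at least 2-fold lower and 8 lay between. Trp53inp1 was 12.4-fold higher, Zmat3 5.59-fold and Eda2r 5.45-fold. Fas, a death receptor, was at 8.09 in the knockout and 4.19, below background, in the wild type, and it was 8.20-fold higher with low values raised to the background percentile. Cdkn1a, the cyclin-dependent kinase inhibitor p21, went from 9.34 to 11.24, and Mdm2, the ubiquitin ligase that degrades p53, from 9.22 to 11.05. Btg2, Polk, Sesn2 and Ccng1 were the other members at 2-fold or more, and the kinase gene Plk3 was lower, with a difference of -1.25. The list's median difference was 1.13, above all 10000 random lists, whose central 95% ran from -0.17 to 0.19. Random lists held an average of 0.581 genes at least 2-fold higher.

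Genes of G2 phase and mitosis were lower in the knockout sample in a shared direction and by varying amounts. All 18 measured members had a lower value, from 1.05-fold for Ccna2, cyclin A2, and 1.15-fold for the kinase gene Cdk1 to 2.17-fold, with a median difference of -0.70 (1.62-fold), below all random lists. Only Cdc20, an activator of the anaphase-promoting complex, at that upper end, and the spindle checkpoint kinase gene Bub1b, at 2.03-fold, reached a 2-fold difference. The mitotic kinesin gene Kif20a was 1.94-fold and the proliferation marker Mki67 1.93-fold lower. For S phase and replication genes the difference was smaller, with a median of -0.15 (percentile 2.37), 18 of 20 members lower and none at 2-fold. Against random lists not matched on level its percentile was 3.42, inside the central 95%. Ccne1, cyclin E1, was 1.94-fold lower and the helicase subunit gene Mcm5 1.31-fold lower. Among 6 genes of cyclin-dependent kinase inhibitors, Cdkn1a was 3.75-fold higher, while Cdkn2c was 2.91-fold and Cdkn2a, the locus of p16 and p19ARF, 2.62-fold lower. That list's median was -0.55 (percentile 0.14).

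**Figure D2:**
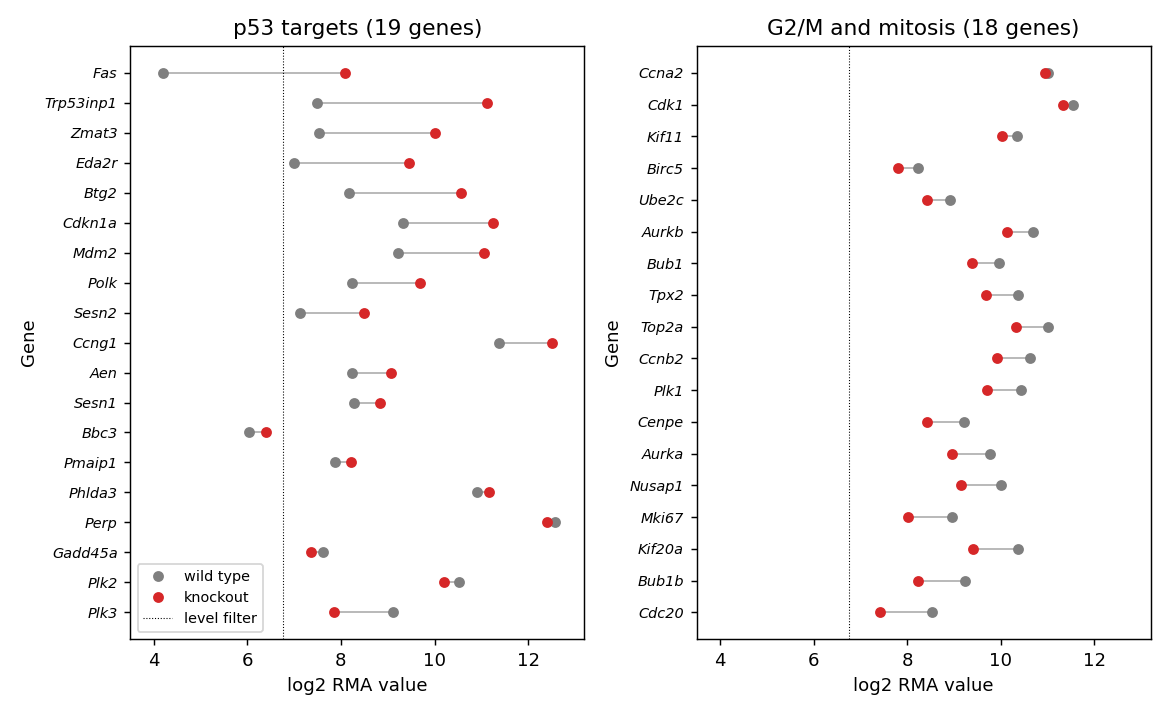
Log2 RMA value (x axis) of each measured gene of the p53 target list (left, 19 genes) and of the G2 phase and mitosis list (right, 18 genes) in the wild-type sample (grey) and the knockout sample (red); each point is 1 array and the dotted line is the level filter at 6.76. The red points lie to the right for most p53 targets, with a median difference of 1.13, and to the left for all 18 mitotic genes, with a median of -0.70.

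Inflammatory and mucosal defence genes were on balance higher in the knockout sample. Of 22 measured NF-kB targets, 14 had a higher value and 8 a lower one. Among those above the level filter, 4 were at least 2-fold higher and 1 was at least 2-fold lower. The list's median difference was 0.36, above all 10000 random lists. Il1a, an alarmin cytokine, was 5.55-fold higher, the neutrophil chemokine gene Cxcl5 5.03-fold and Csf3, granulocyte colony-stimulating factor, 2.35-fold, while Ptgs2, cyclooxygenase-2, was 4.23-fold lower. Tnfaip3, a feedback inhibitor of NF-kB, differed by 1.05. Cxcl5, Csf3 and Tnfaip3 passed the level filter by their knockout values only (wild-type values 6.67, 5.76 and 6.64). Among 12 mucosal defence and acute phase genes, 11 had a higher value (median 0.30, percentile 99.9), but only Lcn2 and Slpi, an antiprotease at 12.3-fold, were above the level filter. Both passed it by their knockout values only (wild-type values 5.67 and 6.69), which favours a higher knockout value. The wild-type value of Slpi lay just under the filter, so passing it required little rise. With knockout values of 11.37 for Lcn2 and 10.31 for Slpi, the differences of 5.70 and 3.62 were larger than passing required. With values raised to the background percentile this list's median was 0. The 16 genes of the STAT3 pathway had a median of 0.17 (percentile 93.8), and 1 of them, the oncostatin M receptor gene Osmr at 3.02-fold, was at least 2-fold higher. Stat3 itself differed by 0.43.

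Interferon response genes were lower in the knockout sample. Their median difference was -0.32 (percentile 0.04), 15 of 20 members had a lower value, and 2 of the 6 above the level filter were at least 2-fold lower. Rsad2, an antiviral enzyme, had a knockout value below background and was 3.35-fold lower with that value raised to the background percentile. The transcription factor gene Irf9 was 2.21-fold lower, while Stat2 was 1.54-fold higher. Oasl2 and Ifit1 were below the filter; Ifit1 differed by -1.27, and Oasl2, with a knockout value below background, by -1.54 with that value raised to the background percentile. Raising low values to the background percentile reduced the median to -0.067. The 9 antigen presentation genes had a median of -0.03 (percentile 45.9) and none above the filter reached 2-fold. In that list the peptide transporter gene Tap1 was 1.95-fold higher and Psmb10, an immunoproteasome subunit, 1.52-fold lower.

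Receptors and ligands of the ERBB family had a median difference of 0.29 (percentile 98.5) over 10 measured genes. Egfr, the epidermal growth factor receptor, was 2.13-fold higher in the knockout sample, at 8.61 and 9.70, and was the single member at 2-fold or more in that direction. The ligand gene Tgfa was 1.69-fold and Hbegf 1.40-fold higher, while the ligand gene Epgn was 4.96-fold lower. The mean of the list was 0.11. The 19 MAPK feedback and immediate early genes had a median of 0.06 (percentile 69.8). Spry1, an inhibitor of receptor tyrosine kinase signalling, was 2.20-fold higher and the phosphatase gene Dusp4 3.95-fold lower.

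Markers of airway basal cells were bright in both samples, with list medians of 10.97 in the wild type and 10.87 in the knockout. Their median difference was -0.08 (percentile 22.0), and among 16 measured genes only Pdpn reached 2-fold. Krt17 was 1.31-fold lower and Krt15 1.61-fold higher in the knockout sample. Among 20 squamous and cornified envelope genes (median -0.11, percentile 16.5), Sprr2d, whose wild-type value of 3.75 was below background, was 6.84-fold higher with low values raised to the background percentile, and Sprr1b was 18.1-fold lower, both from a family of close paralogs, and the matrix protein gene Ecm1 was 3.16-fold lower. Among 23 epithelial junction and identity genes, 4 were at least 2-fold higher and none lower, and 0.22% of random lists held as many higher genes. These were Krt18, Dsg2, the claudin gene Cldn7 at 5.80-fold and the epithelial transcription factor gene Elf3 at 2.26-fold. Krt18, Dsg2 and Cldn7 passed the level filter by their knockout values only (wild-type values 5.15, 3.90 and 5.66). That list's median was 0.03 (percentile 78.0), and all other members differed by less than 2-fold.

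Among markers of club and ciliated cells, Cyp2f2, Ltf and Foxj1 were at least 2-fold higher in the knockout sample, and most members of both lists were dim. All 3 passed the level filter by their knockout values only. Of 16 club and secretory cell genes, 4 were above the level filter and 2 were at least 2-fold higher, namely Cyp2f2, a cytochrome P450 of club cells, at 8.86-fold, and Ltf, lactoferrin, whose wild-type value was below background, at 4.83-fold with that value raised to the background percentile. Wfdc2 was 1.5-fold and Cbr2 1.43-fold higher, and the list's median was 0.12 (percentile 98.51). This median was 0.0 with values raised to the background percentile, and its percentile was 94.4 against random lists not matched on level. Of 15 ciliated cell genes, the master regulator gene Foxj1 was the single member above the filter, at 6.70-fold higher (median of the list -0.04, percentile 57.1, mean 0.21). None of 7 goblet cell genes (median -0.27, percentile 3.25) and none of 9 genes of rare airway cell types (median -0.08, percentile 48.1) was above the filter. The brightest goblet cell gene, Spdef, was at 6.07 and 5.80, and the brightest rare-cell gene, Foxi1, at 6.54 and 6.35. Among 10 alveolar genes (median -0.20, percentile 5.41), the water channel gene Aqp5 was 2.51-fold lower.

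Markers of cells that could accompany epithelium in culture were mostly dim in both samples. None of 13 immune cell genes (median -0.07, percentile 45.5) and none of 12 endothelial genes (median -0.11, percentile 30.1) was above the filter. The brightest were Cd68 in the former, at 6.63 and 6.67, and Egfl7 in the latter, at 6.46 and 6.13. Of 17 cartilage, muscle and thyroid genes (median -0.15, percentile 14.5) only Sox9 was above the filter, 1.36-fold lower. Of 29 fibroblast and mesenchymal genes, 8 were above the filter and differed in both directions. The smooth muscle actin gene Acta2 was 6.86-fold higher. Postn, periostin, and the transcription factor gene Prrx1 had wild-type values below background (4.28 and 4.75) and were 10.6-fold and 5.25-fold higher with low values raised to the background percentile, while Sparc was 8.64-fold lower and Vim, vimentin, differed by -2.24. That list's median was -0.13 (percentile 13.6) and its mean 0.10, so the sign depends on the summary.

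Several signalling and metabolic lists held single genes with large differences. In the WNT and Notch list, 14 of 20 genes were above the level filter. Of these 14 genes, 4 were at least 2-fold lower. As many lower genes were held by 0.03% of random lists drawn to match all 20 genes. Such a share was computed for every list in both directions, and only some are quoted. In the other direction 2, the receptor gene Notch1 at 2.39-fold and its ligand gene Dll1 at 2.07-fold, were higher. Sfrp1, a secreted WNT antagonist, was 8.51-fold, Wnt4 5.65-fold, Wnt10a 4.57-fold and Wnt7a 2.42-fold lower (median of the list -0.14, percentile 6.61). Sfrp1, Wnt10a and Wnt7a passed the level filter by their wild-type values only (knockout values 5.81, 6.62 and 6.00), which favours a lower knockout value. Among members above the level filter the median was 0.15, so its sign depends on which genes are taken. In the TGF-beta list (median 0.01, percentile 65.7), Tgfbi was 5.23-fold lower, and Skil, a SMAD repressor, was 2.36-fold and Id1 2.11-fold higher. Among integrins and matrix proteases (median -0.10, percentile 15.0), Timp3 was higher and the collagen receptor gene Itga2 2.60-fold lower, and the sign turned with the mean (0.21) and with members above the filter (0.18). NRF2 antioxidant genes had a median of 0.21 (percentile 99.1), with 13 of 16 members higher, and the detoxifying genes Gsta3 at 4.84-fold and Ephx1 at 2.47-fold were at least 2-fold higher. In the retinoid list (median -0.01, percentile 57.6) the retinaldehyde dehydrogenase gene Aldh1a1, with a wild-type value below background, was 8.86-fold higher with that value raised to the background percentile, and Rdh10 was 1.75-fold higher. The list's mean (0.29) and its median over members above the filter (0.10) were positive. In the xenobiotic list (median -0.11, percentile 17.99) Cyp1b1 was 10.2-fold lower.

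Housekeeping and general metabolic lists differed little. Reference genes had a median of 0.03 (percentile 63.7), with no member at 2-fold. The unfolded protein response (median 0.05, percentile 76.3), translation initiation (median 0.01, percentile 64.5) and cholesterol synthesis (median -0.10, percentile 17.8) held no gene at 2-fold. In the glycolysis and hypoxia list (median 0.05, percentile 78.9) the oxygen sensor gene Egln3 was 3.19-fold higher and Ndrg1 2.25-fold lower. In all, 6 of the 36 lists lay above the 97.5th percentile and 5 below the 2.5th, against 1.8 expected outside these bounds if list members varied independently. Members of such lists need not vary independently, so these numbers do not show an excess over chance.

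**Figure D3:**
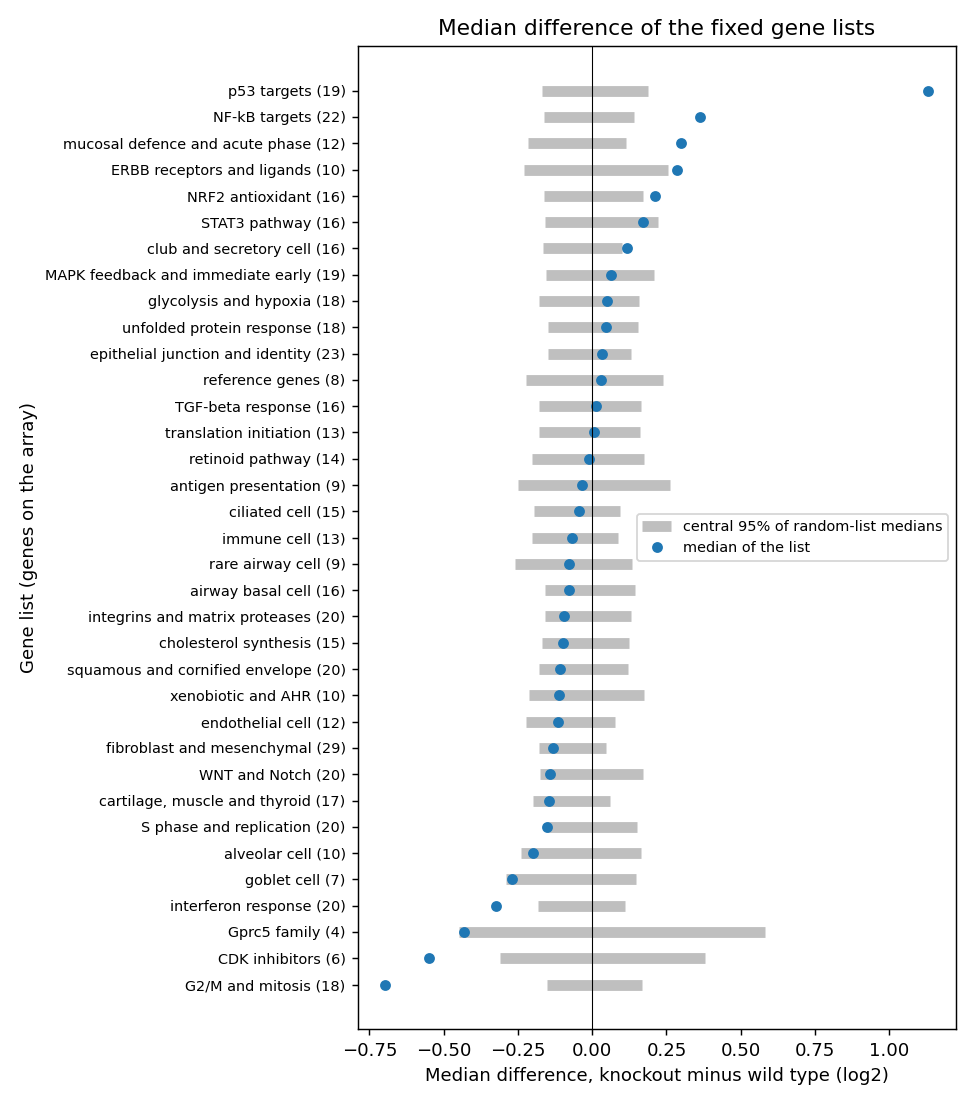
Median difference of each fixed gene list except the sex-linked list, knockout minus wild type on the log2 scale (x axis), with the number of measured genes in parentheses; blue points are list medians and grey bars the central 95% of the medians of 10000 level-matched random lists. The p53 target list lies farthest to the right at 1.13 and the G2 phase and mitosis list farthest to the left at -0.70.

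The Y-linked genes that could be named on the array differed between the samples. Eif2s3y was at 6.19 in the wild-type sample and 2.98 in the knockout sample, and Kdm5d was at 4.62 and 3.37. Both were below the level filter, and Kdm5d was below the background percentile of 5.05 in both samples. The median of this list of 2 genes was -2.23, below all random lists, and -0.57 with values raised to the background percentile, where Eif2s3y alone still differed. The sex of the donor animals is not given in the labels.

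Genes beside the targeted locus were compared because a knockout made in one strain and crossed into another can carry flanking DNA of the first strain. The 20 genes nearest to Gprc5a on chromosome 6, 10 on either side among those on the array, had a median absolute difference of 0.24 (percentile 79.7). Of the 10 above the level filter, Crebl2 was at least 2-fold higher (1.11) and Pbp2, with a knockout value below background, at least 2-fold lower (-2.39, or -1.85 with that value raised to the background percentile). Without the filter 3 genes reached 2-fold, the third being Hebp1, 2 genes from Gprc5a, with a difference of 1.40 and a knockout value of 6.61, just under the filter. With 5 genes on either side the median absolute difference was 0.51 (percentile 97.9), and with 20 on either side it was 0.24 (percentile 94.5). Arhgdib, among the 14 genes with the lowest differences, was the 17th gene on one side. Cdkn1b, the neighbour on the other side, differed by -0.50.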

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

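The tests on dim probe sets (p53 targets and Eif2s3y) and on Cdkn2a reported here were chosen after the results were seen, while the bounds on the scalings and on the X-linked genes were set beforehand. Probe sets that took no part in the comparisons also differed between the samples, which is why they are listed. Of 2215 probe sets without a listed gene that were above the level filter, 49 were at least 2-fold higher in the knockout than in the wild-type control sample and 24 were lower. The sources used here do not state whether the probe sets without a listed gene are control probe sets of the array, and 6577 of all 7317 have ID numbers below 6000000, so these counts are not counts of genes. Of 354 probe sets above the filter that carry several gene symbols, 25 were at least 2-fold higher and 12 lower.

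Of the 36 fixed lists, the p53 targets had the highest median difference. Over loess, centring and quantile normalization the lowest median of the p53 list was 1.07, against a bound of 0.5 set beforehand. For centring and quantile normalization this outcome was nearly fixed, as the sorted deposited columns already differed by at most 0.17. Whether scaling contributed is therefore not decided. Loess, which removes a trend of the difference with level, left a median of 1.14, which argues against such a trend as the cause. Dim probe sets were argued against, since the 17 members with both values above the level filter had a median of 1.13. It stays open whether the pattern goes with the loss of Gprc5a or with a difference in p53 activity between the samples that is unrelated to it, such as a change acquired by the wild-type cells during growth. Cdkn2a, which p53 is known to repress, was lower in the knockout sample by a difference of -1.39, a direction that both explanations would give, and with 1 array per genotype, from a number of animals or cultures that the labels do not give, they cannot be told apart.

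The Y-linked genes point to another difference between the samples, though above background the pattern rests on Eif2s3y alone: Kdm5d, at 4.62 and 3.37, was below the background percentile of 5.05 in both samples, and with values raised to that level the list's median went from -2.23 to -0.57. The wild-type value of Eif2s3y lay 1.13 above the 95th percentile of the receptor genes, though below the level filter. As a value of 1 gene on 1 array, it carries only little weight against background alone. Donors of different sex, or loss of the Y chromosome from the knockout cells, may each account for the lower Y-linked values. X-linked genes with a Y-linked partner or known escape from inactivation had a median difference of 0.14 over 6 genes, all 6 with a higher knockout value (percentile 86.4), which lies between the bounds of 0.1 and 0.3 set for the explanations, so they cannot be told apart. If the donors differed in sex, sex would be confounded with genotype throughout.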

How the results depend on the processing

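No paired analysis was possible because each group holds 1 sample, and for the same reason no replicate could be left out. Median centring, loess, quantile normalization and the mean over probe sets moved no list's median by 0.1 or more and neither count by over 1.5 times. For list medians under centring this was fixed in advance, because centring shifts every gene by the same 0.059. The mean over probe sets can alter only the 135 genes with more than 1 probe set. As the sorted deposited columns differed by at most 0.17, quantile normalization could also change little. Under centring, 330 of the 367 higher genes remained and all 236 lower genes were among 264. Under quantile normalization the counts were 324 and 268. Of the 144 named genes other than Gprc5a, 9 moved by 0.1 or more under quantile normalization, 80 with the offset and 26 with the background floor, and none of these changed sign. Medians near 0 changed sign with a move of less than 0.1 under centring for the epithelial junction, glycolysis, unfolded protein, translation, TGF-beta and reference gene lists, under loess for the MAPK and TGF-beta lists, under quantile normalization for the MAPK, translation, TGF-beta and reference gene lists, and under the background floor for the TGF-beta list. Cd68 did so under centring, loess and quantile normalization (-0.025, -0.0097 and -0.059), and Sox18 under loess. With the 75th percentile as filter 151 genes were higher and 98 lower, at 1.5-fold 874 and 612, and at 3-fold 174 and 118. With the offset, which shrinks dim genes by construction, the difference of Gprc5a was -3.95, the neighbours' median 0.099, and the list medians were -0.15 for goblet cell, -0.066 for alveolar, 0.26 for NF-kB, -0.19 for interferon, 0.067 for mucosal defence and -0.91 for sex-linked genes. With values raised to the receptor background (chosen after seeing the data), Gprc5a differed by -4.43, the neighbours' median was 0.10, the interferon median -0.067 and the sex-linked median -0.57. The medians of the club cell, goblet cell, alveolar, fibroblast, endothelial, cartilage, mucosal defence and xenobiotic lists became 0.0, as most of their members are dim. Those of the ciliated cell, rare-cell, immune, antigen presentation, retinoid, translation initiation, and integrin and protease lists also became 0.0, with a move of less than 0.1. Restricted to members above the level filter, the sign changed with a move of 0.1 or more for the ciliated cell (2.74, 1 gene), fibroblast (0.26), retinoid (0.10), integrin and protease (0.18) and WNT and Notch (0.15) lists. Where few members pass, this restriction favours genes that differ, because it takes the higher of the 2 values. Under it the medians were -0.59 for squamous, 1.61 for club cell, -0.77 for alveolar, -0.44 for cartilage, 0.68 for NF-kB, -0.64 for interferon, -0.42 for antigen presentation, 4.66 for mucosal defence (2 genes), 1.24 for p53, 0.32 for NRF2 genes and 0.38 for the neighbours, and translation initiation changed sign within the tolerance (-0.021). The goblet, rare-cell, immune, endothelial and sex-linked lists had no member left. The mean in place of the median changed the sign, with a move of 0.1 or more, for the ciliated cell (0.21), fibroblast (0.098), retinoid (0.29) and integrin and protease (0.21) lists, and with a smaller move for the immune cell (0.0079), MAPK (-0.027), TGF-beta (-0.014) and reference gene (-0.026) lists. It gave -1.65 for the Gprc5 family, -0.34 for basal, -0.24 for squamous, 0.46 for club, -0.17 for goblet, 0.62 for epithelial junction, -0.49 for interferon, 1.096 for mucosal defence, 0.11 for ERBB, -0.38 for CDK inhibitor, 0.37 for NRF2, -0.42 for xenobiotic, 0.22 for glycolysis and -0.45 for WNT and Notch genes, and 0.45 for the neighbours. With 5 genes on either side the neighbours' median was 0.51. Against unmatched random lists 32 of 36 percentiles stayed on the same side of the 2.5th and 97.5th, the club cell and S phase lists came inside (94.4 and 3.42) and the Gprc5 family and STAT3 lists went outside (1.45 and 97.95). The cause of these changes was not tested, other than by the construction named.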

Other observations

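Collagen genes above the level filter, which were not among the fixed lists as a family, were on balance lower in the knockout sample. Of 10 collagen genes above the level filter, 5 were at least 2-fold lower and none was at least 2-fold higher, with a median difference of -1.11. They included chains of basement membrane collagen, with Col4a1 3.01-fold, Col4a3 3.497-fold and Col4a4 2.89-fold lower, and Col7a1, the anchoring fibril collagen, 2.99-fold lower. Col17a1, a hemidesmosome collagen, was 1.05-fold lower and Col18a1 1.45-fold higher. Col12a1, Col4a3, Col4a4 and Col7a1 passed the level filter by their wild-type values only, which favours a lower knockout value. Their knockout values were 5.80, 5.73, 6.12 and 6.30. Collagen genes of the fibroblast and cartilage lists below the filter differed less, from -0.31 (Col6a2) to -0.04 (Col2a1). Interleukin and interleukin receptor genes above the filter went the other way, with a median of 0.58 over 16 genes and 3 at least 2-fold higher. These were Il1a, Il1f9 (as the platform names it) and the receptor gene Il18r1. The wild-type values of Il1f9 and Il18r1 were below the background percentile of 5.05, and raised to it the genes were 6.60-fold and 4.19-fold higher. Both passed the level filter by their knockout values only. Among interleukin genes below the filter, Il1b differed by -0.33, Il6 by 0.0045 and Il11 by 0.04. Among 9 Sox transcription factor genes the median was -0.44, and Sox15 was 3.10-fold lower. These families were found after seeing the data, by grouping the genes by the start of their symbol. Of 130 such families with at least 8 genes above the filter, 8 lay below the 2.5th percentile of random lists and 3 above the 97.5th. If family members varied independently, 6.5 would be expected outside by chance. The percentile was 0.0 for the collagens, 0.16 for the Sox genes and 99.99 for the interleukins.

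The imprinted genes Peg3, Sgce and Grb10 were all lower in the knockout sample, with differences of -3.23, -5.31 and -3.19 (-2.97 and -4.12 for Peg3 and Sgce with their knockout values, below background, raised to that level), which was noticed in the data. A shared shift of imprinted genes was tested as a hypothesis on 26 other imprinted genes, with the bound set before their values were seen. Among level-matched random lists their median had a percentile of 49.82, which argues against a shift of the whole class, but carries little weight because 17 of the 26 were below the level filter, where a lower value could hardly be seen. Of the 9 that were above the level filter, 7 lay within 0.5 of 0, and the median of the 9 was -0.03. Phlda2, at 5.28-fold, and Slc22a18, at 2.52-fold, were lower. That is 2 of 9 genes, while 2.97% of all genes above the filter were at least 2-fold lower. Most of the 9 thus showed no shift, but so few genes do not settle whether imprinted genes were lower more often than others. Ndn, just under the filter, went the other way, from 4.86, below background, to 6.73, or 3.20-fold higher with low values raised to the background percentile. Phlda2 and Slc22a18 are neighbouring imprinted genes, and what they share with the 3 genes first noticed was not tested.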
